A study of Mus musculus with 11 samples.

How the data were processed

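RNA was measured in 11 libraries from C57BL/6 mice: 4 of tumor-associated macrophages of Sin1-floxed mice without Cre (WT_TAM), 4 of tumor-associated macrophages of mice with LysM-Cre and the same floxed gene (KO_TAM), and 3 of splenic macrophages of the mice without Cre (WT_SP). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were sorted by flow cytometry 14 days after subcutaneous injection of Lewis lung carcinoma cells, a mouse lung tumor line, and total RNA was extracted with Trizol. Per the submitters' processing notes, the build was mm10 and the tools were TopHat2, HISAT2, HISAT, SAMtools, HTSeq and DESeq2. Their roles, versions and settings, the strand setting and the annotation are not given in the sources used here.

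The authors deposited 2 tables, 1 for the genotype comparison with 35118 genes in 8 libraries and 1 for the site comparison with 35597 genes in 7 libraries, and the WT_TAM libraries are in both. The deposited values are not read counts, although the tables' names call them that, so they were treated as a score with no fixed range. The deposited values hold decimals, and 12205 genes of the genotype table and 12492 of the site table have only values at or below 0. Every numeric column was used, so 0 were left out.

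From the values, a cell was found to equal a whole number of reads divided by the gene's length and by the library's total and factor. It was then multiplied by 1 of the libraries' factors taken in turn down the rows. Exceptions were 98 cells in 35 genes of the genotype table and values of 4 genes not settled, both described below. Genes without a length had been divided by -1, which gives the negative values of 13573 genes over both tables. The reads were recovered from the steps between low values and from the 33340 genes in both tables. A value counted as whole within 0.0002 reads, or within 1e-07 of its size. A gene with a value in the site table that was not whole counted as not settled. There were 4 such genes, which were left out, so the 169580 non-zero values of the site table in the other genes are whole by this choice. The recovered reads made up between 99.9% and 100.0% of the total that each library's scale implies. The settings of this recovery were settled on the tables themselves, after they had been looked at.

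In the genotype table, 98 values in 35 genes were not whole reads. The 49 of these in WT_TAM libraries were replaced by the reads of the same library in the site table. The 49 in KO_TAM libraries became whole, within 1e-05 reads, after exactly 1 of 54 round amounts was taken off or added back. The resulting reads were used for all but 2 of them. For these 2 KO_TAM cells, both of Fdps, a value with 1 digit put back was a second candidate. The match of the size factors chose it, which gave 15 reads in KO_TAM replicate 1 and 14 in KO_TAM replicate 3. In 8000 control cells shifted by a random part of a read, 5 became whole after such an amount. Size factors computed from the restored reads by median of ratios matched the factors in the table to 5.12e-11 on the natural log scale, against 0.000442 with the cells as deposited. Treating the KO_TAM cells as missing was the first plan. The restored reads became the main treatment after all 3 treatments had been run, because of this match and because missing cells would leave mostly KO_TAM replicate 2 in some genes.

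Because the deposited unit is not counts, the planned edgeR test was not used, and the DESeq2 alternatives were not run. Neither was run on the recovered reads. Instead, log2 of CPM plus 0.5 was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes. CPM were relative to the library total times the authors' factor. Fold changes are on this log2(CPM + 0.5) scale, which understates changes of low genes. A gene was tested if it had the CPM of 10 reads at the median library size in at least as many libraries as the smaller group, and at least 15 reads in all. Each comparison used its own 2 groups and its own table, with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All tests were two-sided. Levels of a library in the 2 tables differ by their factors and are compared only within a table.

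The 41 gene lists with 779 genes (24 of pathways, 13 of cell types and 4 of RNA quality), the groups, the comparisons, the test of summed markers and the settings listed first below were fixed before the data were examined. The test of genes and the test of lists are not the planned ones. Lists with at least 3 tested members were tested against all other genes with limma's cameraPR on the moderated statistics, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 40 lists. The list of sex-linked genes had fewer and was only summed. Camera with an estimated correlation and fry were run as alternatives. Camera on voom values had been planned and was replaced for the same reason as the gene test. Summed CPM of the cell type and quality lists were compared by an exact permutation test of the group means, adjusted over 17 lists.

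Genes were named by a rule: Mapkap1; the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 2 and groups that do not overlap; up to 4 called members of each pathway list, or its most abundant member where none was called; the 2 most abundant members of each cell type or quality list; and 17 genes set in advance. Predicted genes, pseudogenes, receptor segments and rows without a symbol were left out of the largest changes. Any other gene named was chosen after its values were seen, which is said beside it. The text names only part of the genes that the rule gives, a choice made after their values were seen, and some genes are not reported here.

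The settings tried as set in advance were voom, median-of-ratios and upper-quartile factors, no filter, at least 1 CPM in at least 3 libraries, the replicate number as a block, all groups in 1 fit, an absolute log2 fold change of at least 1, and leaving out each library in turn. Median-of-ratios factors proved to be the authors' own, so that setting repeats the main values and tests nothing further. Ranges of adjusted p over alternatives leave it out. Added after the data were seen were pseudocounts of 0.25 and 2, library factors left out, array weights, the deposited values as they stand, the altered cells as deposited or missing, and leaving out WT_TAM replicate 4 and KO_TAM replicate 2 together. The deposited values as they stand were tested with a pseudocount of 0.1, without the genes that carry negative values.

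The recovery of reads, the limma trend fit and camera with the preset correlation were tested on simulated data. The other tests were not tested in this way. In a simulation of the genotype comparison over 12875 genes with 200 changed, limma called 47% of the genes changed 2-fold and 90% of those changed 4-fold, and 137 of the 144 calls were changed genes. For the site comparison over 14239 genes, these shares were 40% and 92%, with 132 of 138 calls changed. Simulated genes were drawn independently, with a spread set by a trend over level and no library unlike its group. The real data differ in this, so these shares can overstate what limma finds there. In a simulated pair of tables with 12958 genes, all 62 altered cells were found, 32 of 32 in KO_TAM libraries were restored exactly, and 0 other cells were called altered. These were made by amounts among those searched for and only in well-read genes. Digits left out and genes with few reads, as among the real altered cells, were not covered.

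Gene positions are from GENCODE M21 on GRCm38, the assembly also called mm10, which held 37117 of the 37371 gene IDs used (99.3%). Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.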

Results

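Transcripts were measured by RNA sequencing in macrophages from mice that carried Lewis lung carcinoma, a transplantable mouse lung tumor. Sin1, the product of the gene Mapkap1, is a subunit of mTOR complex 2, the kinase complex that phosphorylates AKT and SGK1. The gene was floxed, and LysM-Cre, which is expressed from the Lyz2 locus, deletes floxed genes in the myeloid lineage. There were 4 libraries of tumor-associated macrophages without Cre (WT_TAM), 4 with Cre (KO_TAM) and 3 of splenic macrophages without Cre (WT_SP). Tumor-associated macrophages were sorted as CD45+ Ly6G- Ly6C- CD11b+ F4/80+ cells, and splenic macrophages as TCRβ- Ly6G- Ly6C- F4/80+ cells with low CD11b. The labels do not say that each library is a separate mouse, so p-values measure the spread between these libraries, which may be technical.

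Recovered reads numbered 13075539, 12317491, 12055551 and 7635598 in WT_TAM replicates 1 to 4, 13091886, 9858795, 11410455 and 10509882 in KO_TAM, and 11812375, 10630556 and 11326461 in WT_SP. At these depths 3 reads corresponded to between 0.220 and 0.465 CPM in the tumor libraries, a limit that covers counting error only. Pairs of libraries of each group differed by more than sampling noise, so none was counted as a repeat of another.

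Mapkap1, on chromosome 2 from 34406771 to 34624950 on the plus strand (GRCm38), was read in every library. Its level was 71.1, 66.4, 59.7 and 30.7 CPM in WT_TAM replicates 1 to 4 and 44.0, 54.1, 43.3 and 45.9 CPM in KO_TAM. The KO_TAM mean of 46.8 ± 4.96 CPM (SD, n = 4) did not differ from the WT_TAM mean of 57.0 ± 18.1 CPM (SD, n = 4), with a log2 fold change of -0.22 ± 0.26 (SE) and a limma adjusted p of 0.658. Without WT_TAM replicate 4 the change was -0.49 (limma adjusted p = 0.163), and the other WT_TAM libraries all lay above all KO_TAM libraries. Over alternatives the limma adjusted p ranged from 0.0522 with array weights to 0.875 without WT_TAM replicate 1. The deleted exon is not given in the sources used here and the values are per gene, so reads from exons outside the deletion could be counted, and this check of the labels is limited. In WT_SP the level was 59.6 ± 3.4 CPM (SD, n = 3). WT_TAM did not differ from it with all libraries (log2 fold change 0.03 ± 0.31, SE; limma adjusted p = 0.939), but was higher without WT_TAM replicate 4 (0.33; limma adjusted p = 0.0168, range 0.0168 to 0.987 over alternatives). Rictor, another subunit of mTOR complex 2, had 65.8 ± 7.67 CPM in KO_TAM and 42.4 ± 15.5 CPM in WT_TAM (SD, n = 4 each; limma adjusted p = 0.249), a log2 fold change of 0.72, or 0.39 without WT_TAM replicate 4. Mtor, the kinase itself, had 27.0 ± 4.18 and 29.0 ± 2.19 CPM (limma adjusted p = 0.75).

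**Figure D1:**
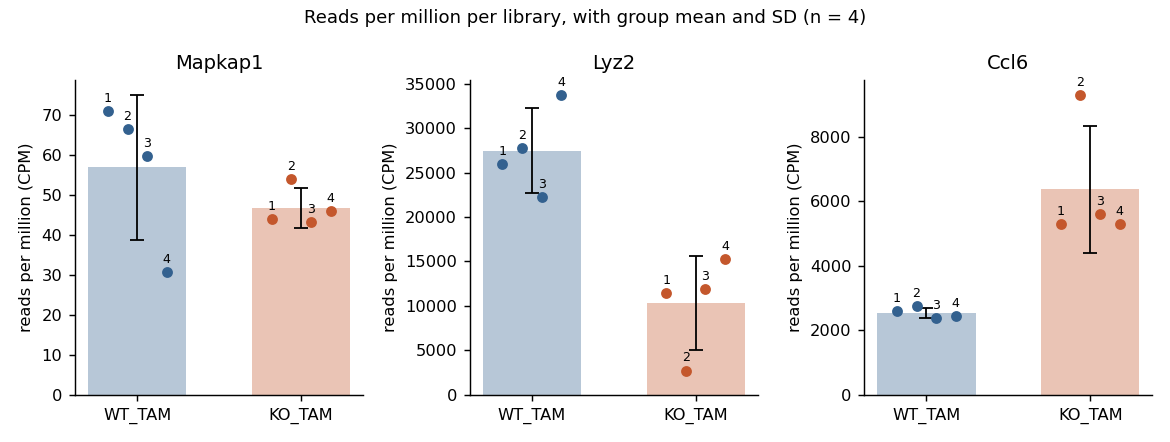
CPM (vertical axis, from 0) of Mapkap1, Lyz2 and Ccl6 in the 4 WT_TAM and 4 KO_TAM libraries. Points are libraries with their replicate number, bars are group means and error bars are SD. Mapkap1 overlaps between the groups, while all KO_TAM libraries lie below WT_TAM for Lyz2 and above it for Ccl6, and neither gene passed the limma test.

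The first comparison, KO_TAM against WT_TAM, asks how loss of Sin1 in myeloid cells changes tumor macrophages, in a series about their anti-tumor activity. Genes of cell division and of cholesterol synthesis were lower as groups in KO_TAM, with median log2 fold changes of -1.01 over 34 genes (-0.62 without KO_TAM replicate 2) and -0.78 over 25 genes. Collagen and other fibroblast genes were lower by a median of -1.88, and transcripts of the mitochondrial genome by -2.02 (-1.19 without WT_TAM replicate 4 and KO_TAM replicate 2). Inflammatory cytokines and mediators were higher as a group, with a median of 0.79 over 21 genes, or 0.51 without WT_TAM replicate 4 and 0.45 without KO_TAM replicate 2 as well. Among them was Nos2, which encodes inducible nitric oxide synthase, at 1056 ± 452 against 299 ± 169 CPM (SD, n = 4 each). Genes of the type I interferon response had a median of 0.29 over 68 genes, which was 0.04 without WT_TAM replicate 4 and -0.01 without KO_TAM replicate 2 as well. No single gene passed the test. The group calls rest on a preset correlation between genes, as 0 of 16 lists were called with an estimated one and only 1, neutrophils, by fry.

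Of 12875 genes tested with limma trend, 0 were higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 0.102. At an unadjusted p of 0.05, 2368 genes (18.4%) differed, and 1948 genes (15.1%) had groups that did not overlap, where chance gives 2.86%. limma voom also called 0 genes, with 2228 at that unadjusted p. WT_TAM replicate 4 and KO_TAM replicate 2 lay apart from the other libraries of their groups, and in tests chosen after this was seen, limma called 65 genes without both and 387 with a weight per library. Without a filter on low reads the count was 98, and with WT_SP in the same fit 83.

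Cells in division were marked by 34 genes of DNA replication and mitosis, all of which had a lower mean in KO_TAM, and 20 were lower when adjusted over the list alone. That count was 0 without WT_TAM replicate 1, 2 or 3 and 13 without KO_TAM replicate 2. The median of -1.01 was -0.62 without KO_TAM replicate 2. Mcm6, part of the replicative helicase, had 97.3 ± 27.2 CPM in KO_TAM and 149 ± 25.2 CPM in WT_TAM (SD, n = 4 each), a log2 fold change of -0.64 ± 0.23 (SE). The list had a camera adjusted p of 1.56e-11, and adjusted p = 0.432 with an estimated correlation, range 9.49e-22 to 0.432 over alternatives. Cholesterol synthesis genes gave 13 lower of 25 adjusted over the list alone, with an adjusted p of 9.22e-09, and adjusted p = 0.432 with an estimated correlation, range 1.59e-15 to 0.432 over alternatives. Leaving out 1 library changed that count of 13 to 6, 5, 4 and 22 for WT_TAM replicates 1 to 4 and to 3 and 4 for KO_TAM replicates 2 and 3. Srebf2, the transcription factor that drives this pathway, had a log2 fold change of -0.58 ± 0.17 (SE), and Cyp51 and Fdft1, 2 enzymes of the pathway chosen here after their values were seen, had -1.03 ± 0.34 and -1.13 ± 0.23. Fatty acid synthesis genes had a median of -0.31 over 19 genes, 0 of them past the threshold adjusted over the list alone (adjusted p = 0.00715, and adjusted p = 0.432 with an estimated correlation, range 0.000281 to 0.432 over alternatives). Without WT_TAM replicate 4 or KO_TAM replicate 4, 4 of them passed. Fasn, fatty acid synthase, had a log2 fold change of -0.86 ± 0.24 (SE) and Srebf1 -0.26 ± 0.21, or -0.16 without WT_TAM replicate 4 or KO_TAM replicate 3. The most abundant member Acly stood at 0.03 ± 0.35, and at -0.36 without WT_TAM replicate 4.

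ATF4 targets of the amino acid response had a median of -0.53 over 18 genes, with 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.00196, and adjusted p = 0.432 with an estimated correlation, range 1.93e-05 to 0.432 over alternatives). Without KO_TAM replicate 2, 4 were lower. The most abundant member of this list, Slc3a2, a subunit of amino acid transporters, stood at 0.17 ± 0.17. Genes of MHC class II presentation had a median of -0.59 over 14 genes, with 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.00483, and adjusted p = 0.482 with an estimated correlation, range 0.000137 to 0.482 over alternatives). The count of 6 was 0 without WT_TAM replicate 1 and 3 without WT_TAM replicate 3, KO_TAM replicate 2 or KO_TAM replicate 4. Cd74, the invariant chain that escorts class II molecules, had 7195 ± 1069 CPM in KO_TAM and 9979 ± 1579 CPM in WT_TAM (SD, n = 4 each), and the 1 member that was higher, Cd80, is a costimulatory ligand and was picked out after its value was seen. Oxidative phosphorylation genes encoded in the nucleus had a median of -0.30 over 26 genes, with 0 past the threshold adjusted over the list alone (adjusted p = 0.000896, and adjusted p = 0.482 with an estimated correlation, range 3.03e-05 to 0.482 over alternatives), and the median was -0.19 without WT_TAM replicate 4.

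Inflammatory cytokines and mediators had 8 higher and 0 lower of 21 adjusted over the list alone, with an adjusted p of 2.73e-06, and adjusted p = 0.432 with an estimated correlation, range 6.12e-09 to 0.432 over alternatives. The count of 8 was 3 without WT_TAM replicate 1 or 3, 0 without KO_TAM replicate 1, and 5 without WT_TAM replicate 4, KO_TAM replicate 2 or KO_TAM replicate 3. The median of 0.79 was 0.51 without WT_TAM replicate 4. Without both libraries that lay apart the median was 0.45 and the count 3. Neutrophil markers and eosinophil, basophil and mast cell markers also summed higher in KO_TAM, at 533 against 160 CPM and 353 against 122 CPM, and the values do not tell which cells the inflammatory genes come from. Nos2 had a log2 fold change of 1.91 ± 0.47 (SE; limma adjusted p = 0.123), and Cxcl2, a neutrophil chemoattractant, had 2277 ± 487 against 1438 ± 234 CPM (SD, n = 4 each), a change of 0.66 ± 0.20 (SE). Genes linked to alternative activation and suppression had a median of 0.30 over 26 genes and 3 higher adjusted over the list alone (adjusted p = 0.00874, and adjusted p = 0.432 with an estimated correlation, range 0.000433 to 0.432 over alternatives). That median was 0.19 without KO_TAM replicate 1 and 0.50 without KO_TAM replicate 2, and 1 gene was higher without WT_TAM replicate 3 or KO_TAM replicate 2. The 3 were Mmp12, a macrophage elastase, Retnla, a marker of alternative activation, and Il1rn, the interleukin 1 receptor antagonist, named after their values were seen. Arg1, the arginine-degrading enzyme of such cells, had 7699 ± 1710 CPM in KO_TAM and 5348 ± 1165 CPM in WT_TAM (SD, n = 4 each), a change of 0.52 ± 0.22 (SE; limma adjusted p = 0.258). Mrc1, the mannose receptor CD206, stood at 0.52 ± 0.29, and Cd274, which encodes PD-L1, at 1.52 ± 0.60 (limma adjusted p = 0.234). These were 0.34 and 0.86 without WT_TAM replicate 4. Ccl6, a macrophage chemokine, was the 1 member of 12 chemokines higher when adjusted over that list alone, at 6370 ± 1959 against 2538 ± 161 CPM (SD, n = 4 each), while the chemokine list had an adjusted p of 0.325.

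The type I interferon list had 50 of 68 members with a higher mean in KO_TAM, and 0 past the threshold adjusted over the list alone. Its camera adjusted p was 0.00701, with adjusted p = 0.691 with an estimated correlation, range 0.000221 to 0.691 over alternatives. The lowest of these came from the deposited values as they stand, which hold altered cells in 9 genes of this list. The call was lost without WT_TAM replicate 4 (adjusted p = 0.275) and without both libraries that lay apart (adjusted p = 0.678). The median was 0.29 with all libraries, 0.04 without WT_TAM replicate 4 and -0.01 without both. Among its genes, Irf7 stood at 0.11 ± 0.27, Isg15 at 0.08 ± 0.21, Ifit1 at 0.77 ± 0.59 and Cxcl10 at 0.04 ± 0.17 on the log2 scale (SE), none past the limma test. Ifit1 stood at 0.09 without WT_TAM replicate 4 and 1.17 without WT_TAM replicate 2. Irf7 fell below 0 without WT_TAM replicate 4 (-0.08) or KO_TAM replicate 2 (-0.03), and Isg15 without WT_TAM replicate 1 (-0.07). The most abundant member Ly6e stood at -0.42 ± 0.19. Ifnb1, interferon beta itself, was read at 0.776 ± 0.548 CPM in KO_TAM and 0.632 ± 0.744 CPM in WT_TAM (SD, n = 4 each), which is near the floor, and was not tested. Interferon gamma induced GTPases and chemokines had a median of 0.52 over 20 genes, 0 past the threshold adjusted over the list alone (adjusted p = 0.00449, and adjusted p = 0.524 with an estimated correlation, range 0.000102 to 0.524 over alternatives). The median was 0.24 without WT_TAM replicate 4, and 3 genes passed without KO_TAM replicate 4. Without both libraries that lay apart the call was also lost (adjusted p = 0.0954), with a median of 0.13. Gbp2, of this list, had a log2 fold change of 0.60 ± 0.21 (SE). Genes of interferon production and nucleic acid sensing had an adjusted p of 0.374.

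Some of the interferon and lipid genes above had values that had to be restored. Of the values for the genotype comparison, 98 in 35 genes were not whole reads, 49 in WT_TAM and 49 in KO_TAM libraries. Of these genes 19 are in the interferon lists, 12 in the lipid synthesis lists and 4 in neither. Of the WT_TAM values, 46 differed from those of the same library in the site table by a whole number, as for Irf1 in WT_TAM replicate 1, deposited as 62.45 where the reads in the site table give 262.45. Interferon list values were lowered in 27 and raised in 3 WT_TAM cells and raised in 29 KO_TAM cells. Lipid synthesis values were raised in 14 WT_TAM cells and lowered in 13 KO_TAM cells. With the cells as deposited, limma called 4 genes, all higher in KO_TAM, where restored reads gave 0. Among them were Tbk1, a kinase that activates interferon factors (log2 fold change 2.20 as deposited, 0.75 restored), Irf1 (2.03 and 0.71) and Chuk (1.95 and 0.74), named after their values were seen. The list of interferon production and nucleic acid sensing then had an adjusted p of 0.00625, against 0.374 with restored reads (range 0.00466 to 0.993 over alternatives). The type I interferon, interferon gamma, cholesterol synthesis and fatty acid synthesis lists were called in the same direction with either. Over the 18 interferon list genes tested, the median log2 fold change was 0.76 as deposited and 0.37 restored, and over the 12 lipid synthesis genes it was -1.17 and -0.81.

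**Figure D2:**
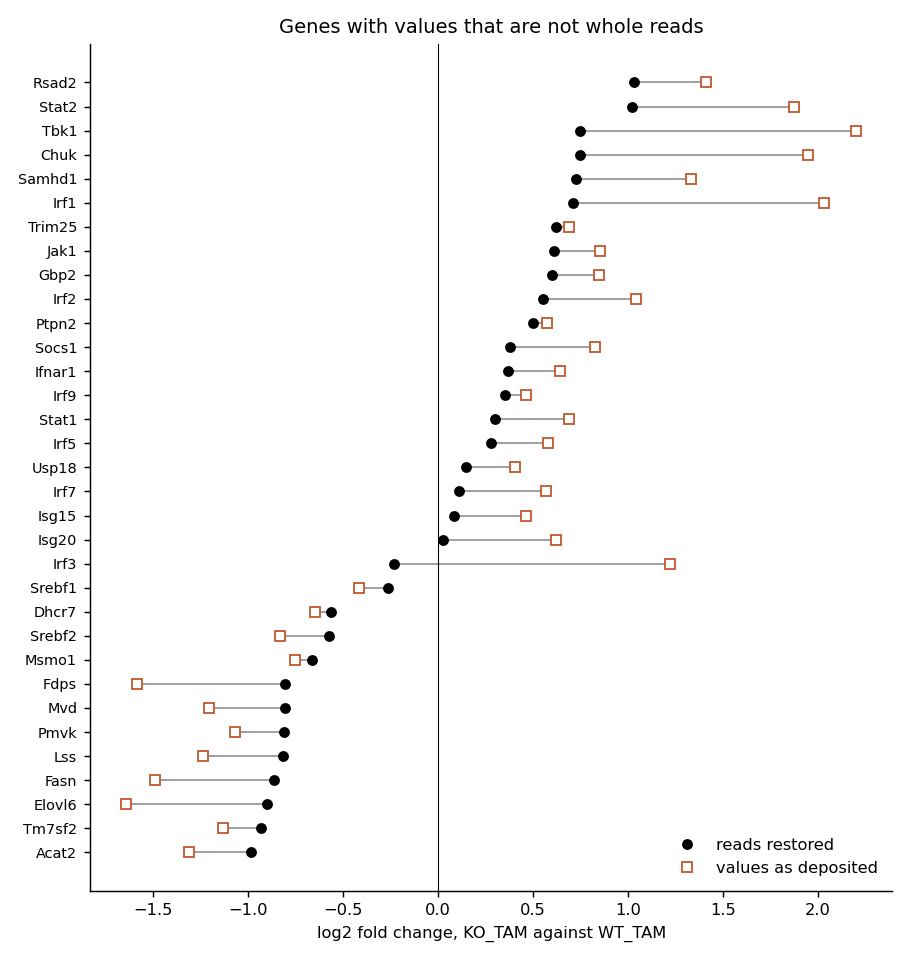
Log2 fold change of KO_TAM against WT_TAM (horizontal axis) for tested genes with values that are not whole reads. Filled circles use restored reads and open squares the values as deposited. The squares of interferon list genes shown lie to the right of their circles and the squares of lipid synthesis genes to the left.

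Macrophage identity genes had an adjusted p of 0.0948, with 1 higher and 5 lower of 20 adjusted over the list alone. Lyz2, which encodes lysozyme and holds the Cre in this line, on chromosome 10 from 117277331 to 117282321 on the minus strand (GRCm38), had 10333 ± 5332 CPM in KO_TAM and 27423 ± 4779 CPM in WT_TAM (SD, n = 4 each). All KO_TAM libraries lay below all WT_TAM libraries (ratio 0.377, exact permutation p = 0.0286, the smallest possible here), and the limma adjusted p was 0.143. The log2 fold change was -1.64, or -1.09 without KO_TAM replicate 2. Reads of Lyz2, of the hemoglobin genes Hba-a1 and Hbb-bs, and of Oas1g could be shared with near-identical copies, so their values are uncertain to that extent. Other lists not called were lipid uptake, storage and efflux (adjusted p = 0.0613), FoxO targets (0.0627, with 3 higher adjusted over the list alone), MHC class I presentation (0.106), the oxidative stress response (0.106) and fatty acid oxidation (0.165). Nor were splenic red pulp macrophage genes (0.233), complement and Fc receptors (0.277), mTOR complexes and AKT (0.325), the lysosome (0.368), the unfolded protein response (0.442), and glycolysis and hypoxia (0.864). Some of these were called when 1 library was left out. Without WT_TAM replicate 2, macrophage identity was lower (adjusted p = 0.0495). Without WT_TAM replicate 4, fatty acid oxidation was lower (0.0372) and the oxidative stress response higher (0.0186). Without KO_TAM replicate 4, lipid uptake, storage and efflux (0.00765), FoxO targets (0.0378), MHC class I presentation (0.0261) and the oxidative stress response (0.0425) were higher. Over alternatives, the adjusted p ranged from 0.0168 to 0.482 for macrophage identity, 0.0372 to 0.432 for fatty acid oxidation and 0.0186 to 0.645 for the oxidative stress response. For lipid uptake it ranged from 0.00765 to 0.432, for FoxO targets from 0.0228 to 0.432 and for MHC class I from 0.0261 to 0.645.

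Fibroblast markers summed to 239 ± 160 CPM in KO_TAM and 1127 ± 476 CPM in WT_TAM (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.121). Their list had a camera adjusted p of 3.07e-08, and adjusted p = 0.432 with an estimated correlation, range 1.17e-13 to 0.432 over alternatives. Of its genes, 9 of 13 were lower adjusted over the list alone, and Sparc and Col3a1 stood at -2.61 ± 0.59 and -2.55 ± 0.65 (SE). Neutrophil markers summed to 533 ± 293 and 160 ± 39.6 CPM (exact permutation p = 0.0286, adjusted 0.121). Of 4 tested genes, 3 were higher adjusted over the list alone (adjusted p = 0.00382, and adjusted p = 0.432 with an estimated correlation, range 0.000662 to 0.432 over alternatives). The list median of 1.43 was 0.90 without WT_TAM replicate 3 and 0.79 without KO_TAM replicate 2. Among the genes were Mmp8 and Retnlg at 2.16 ± 0.43 and 1.77 ± 0.49. Eosinophil, basophil and mast cell markers summed to 353 ± 231 and 122 ± 62.0 CPM (exact permutation p = 0.0286, adjusted 0.121), and their list was not called (adjusted p = 0.494). Platelet genes had 3 of 4 higher adjusted over the list alone (adjusted p = 0.0142, and adjusted p = 0.432 with an estimated correlation, range 0.00254 to 0.432 over alternatives). The list median of 1.42 was 0.94 without KO_TAM replicate 1. The summed platelet markers did not follow, at 526 ± 134 CPM in KO_TAM and 542 ± 317 CPM in WT_TAM (SD, n = 4 each; exact permutation p = 0.914), and the most abundant, Pf4, stood at -0.09 ± 0.38 (SE), or 0.29 without WT_TAM replicate 4. Erythroid genes had 5 of 7 lower adjusted over the list alone, with Hba-a1 at -2.28 ± 0.71. That count was 0 without WT_TAM replicate 2 or 4 or KO_TAM replicate 1, 2 or 4. Their call (adjusted p = 0.00553, and adjusted p = 0.432 with an estimated correlation, range 3.78e-05 to 0.432 over alternatives) was lost without both libraries that lay apart (adjusted p = 0.121).

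Mitochondrial genome transcripts had 12 of 13 lower adjusted over the list alone, with mt-Co1 and mt-Cytb at -1.61 ± 0.59 and -1.8 ± 0.56 (SE; list adjusted p = 4.75e-07, and adjusted p = 0.432 with an estimated correlation, range 6.4e-11 to 0.432 over alternatives). The count of 12 was 0 without WT_TAM replicate 2 or 4 or KO_TAM replicate 1 or 2. The sum of these transcripts was 10688, 68765, 18599 and 68477 CPM in WT_TAM replicates 1 to 4 and 9583 ± 5828 CPM in KO_TAM (SD, n = 4; exact permutation p = 0.0571). Cytosolic ribosomal protein genes had a median of -0.87 over 24 genes, 0 past the threshold adjusted over the list alone (adjusted p = 1.20e-08, and adjusted p = 0.482 with an estimated correlation, range 3.91e-16 to 0.482 over alternatives). The median was -0.46 without WT_TAM replicate 4, and -0.28 without both libraries that lay apart, where 13 genes were lower in the list, as were 24 without WT_TAM replicate 1. They summed to 29660 CPM in WT_TAM replicate 4, between 9425 and 10315 CPM in the other WT_TAM libraries and 7404 ± 1700 CPM in KO_TAM (SD, n = 4; exact permutation p = 0.0286, adjusted 0.121). Of 17 summed marker lists, 0 passed the exact permutation test after adjustment. Lists at the smallest possible p of 0.0286 had an adjusted p of 0.121. A list could pass only if more lists had reached that p, so the count of 0 does not show an equal cell makeup. Not called were B cells (adjusted p = 0.151), dendritic cells (0.170), T cells (0.170), dissociation and immediate early genes (0.529), plasmacytoid dendritic cells (0.531), tumor epithelium (0.531), monocytes (0.669), NK cells (0.832) and endothelial cells (0.987). B cells were higher without WT_TAM replicate 2 (adjusted p = 0.00280), KO_TAM replicate 1 (0.00532) or KO_TAM replicate 2 (0.0426), with a range of 0.00280 to 0.714 over alternatives. T cells were lower without WT_TAM replicate 4 (0.0366) or KO_TAM replicate 4 (0.0267), with a range of 0.0137 to 0.738. Dendritic cells were lower without WT_TAM replicate 4 (0.0156), with a range of 0.0106 to 0.691. Sox9, a factor of the tumor epithelium list, had 17.2 ± 8.28 CPM in KO_TAM and 75.9 ± 22.3 CPM in WT_TAM (SD, n = 4 each; limma adjusted p = 0.102). The more abundant Cdh1 stood at 245 ± 97.2 and 188 ± 76.6 CPM (log2 fold change 0.43, 0.08 without WT_TAM replicate 4 and 0.19 without KO_TAM replicate 1), and the summed markers of that list at 299 ± 90.5 and 278 ± 81.5 CPM (exact permutation p = 0.8). Xist, the 1 sex-linked gene read, had 92.9 ± 27.5 and 73.9 ± 15.9 CPM (exact permutation p = 0.314).

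**Figure D3:**
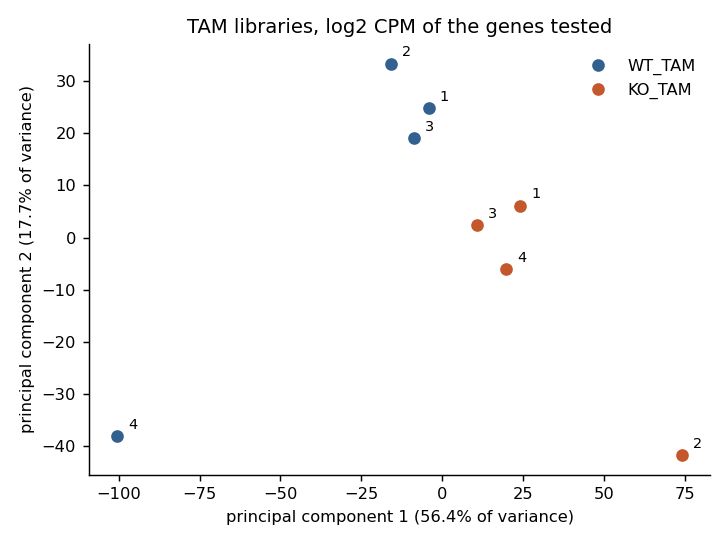
The 8 tumor libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, which held 56.4% and 17.7% of the variance. WT_TAM replicate 4 and KO_TAM replicate 2 lie at opposite ends of the first component.

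**Figure D4:**
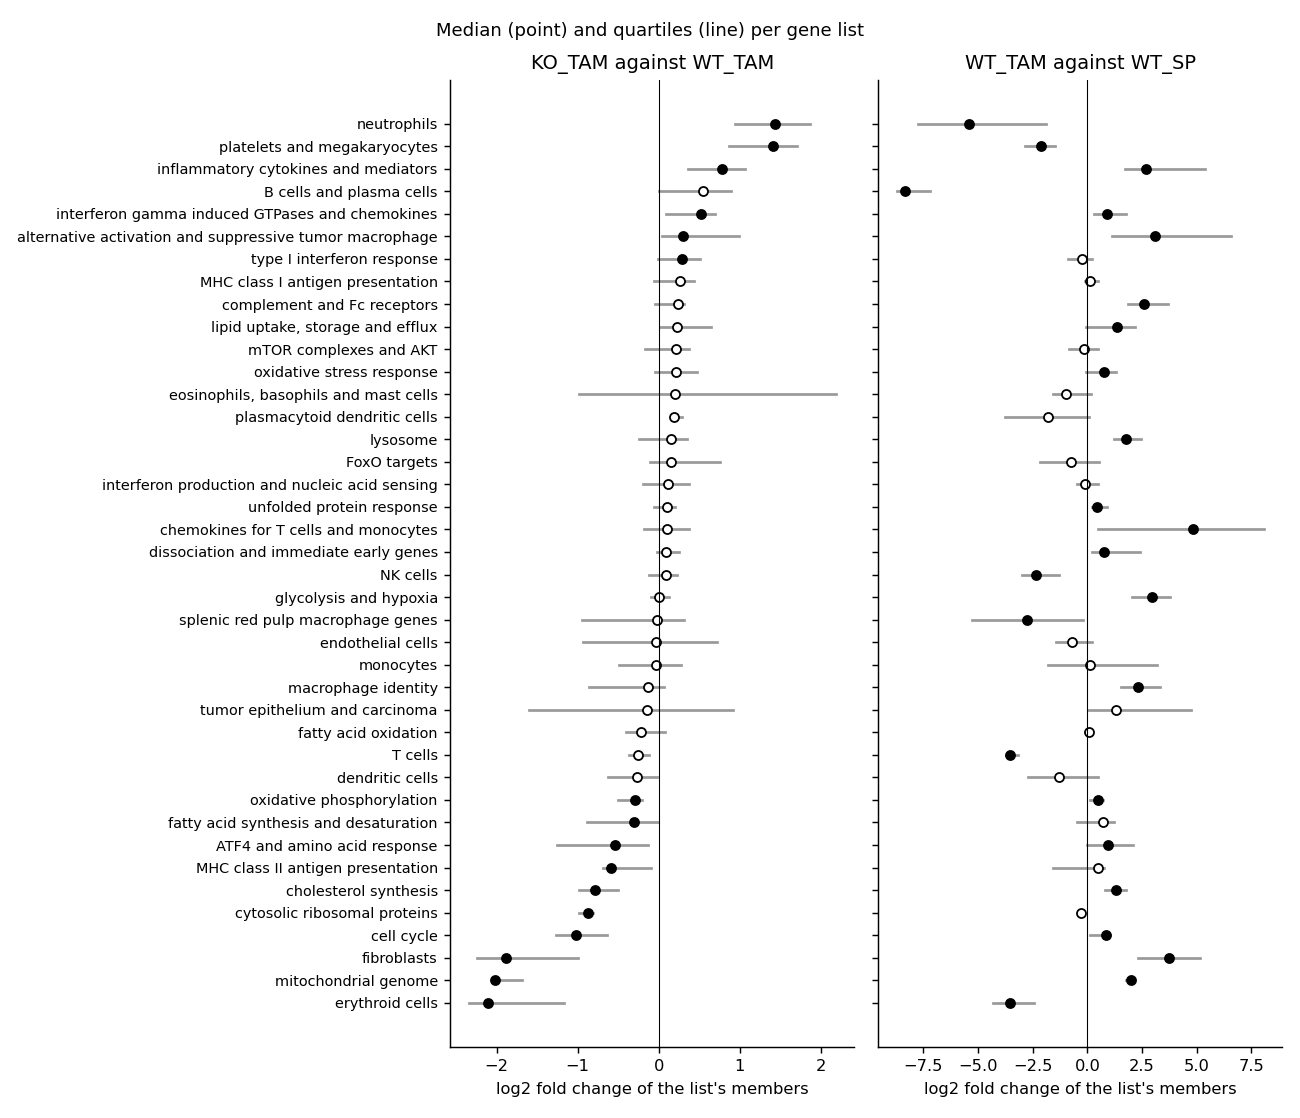
Median log2 fold change (points) and quartiles (lines) of the tested members of each gene list, for KO_TAM against WT_TAM on the left and WT_TAM against WT_SP on the right, with different horizontal scales. Filled points are lists called by camera with the preset correlation, 16 on the left and 25 on the right, and 0 were called with an estimated correlation in either comparison.

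The second comparison, WT_TAM against WT_SP, asks how macrophages in the tumor differ from those in the spleen, and the series names the type I interferon pathway. Tumor macrophages held far more Arg1, at 5991 ± 1184 CPM (SD, n = 4) against 0.854 ± 0.177 CPM (SD, n = 3), a 7013-fold difference, and more Spp1, which encodes the matrix protein osteopontin, at 9449 ± 2987 against 4.06 ± 3.78 CPM. Genes of glycolysis and hypoxia, alternative activation, macrophage identity, lysosomes and inflammatory mediators rose as groups, while the genes of B cells, T cells and red pulp macrophages fell. None of these lists was called with an estimated correlation, with adjusted p from 0.127 to 0.334. Summed B cell markers stood at 153 CPM in WT_TAM against 31811 CPM in WT_SP, and T cell markers at 197 against 2310 CPM. Monocyte, fibroblast and tumor epithelium markers summed higher in WT_TAM. The values do not tell a change within macrophages from a different cell makeup of the sorted samples. The type I interferon list did not move one way: 14 of its 68 genes rose and 17 fell. Cholesterol synthesis genes rose, with 17 higher and 1 lower of 25 by limma, and the list was not called with an estimated correlation (adjusted p = 0.152, range 1.95e-10 to 0.152 over alternatives).

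Of 14239 genes tested with limma trend, 3287 rose and 3364 fell, 5126 of them by an absolute log2 fold change of at least 1. At an unadjusted p of 0.05 there were 7672 genes, and 7993 genes (56.1%) had groups that did not overlap, where chance gives 5.71%. With the library factors left out, an alternative added after the data were seen, 2135 genes rose and 5629 fell, 27.5% against 49.4% higher, as the median of all genes moved from -0.07 to -0.52. Upper-quartile factors gave 57.6% higher. All list calls below were lost with an estimated correlation, and those p are given beside them. The smallest adjusted p of camera with an estimated correlation was 0.127 over all lists. The B cell list was lost too, with all 15 genes lower, so such a loss does not show that a list is unchanged. Fry, which does not weigh a list against the other genes, called 28 lists, 22 of them among the 25 called by camera. The cell cycle, mitochondrial genome and unfolded protein response lists were lost by fry.

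The 8 largest rises named by the rule were Arg1, Spp1, the elastase Mmp12 (log2 fold change 9.54 ± 0.39, SE), Retnla (9.51 ± 0.46), the chemokines Ccl7 (9.48 ± 0.29) and Ccl8 (8.55 ± 0.51), the endocytic adaptor Dab2 (8.78 ± 0.45) and Nos2 (8.61 ± 0.48). Among the 8 largest falls were Jchain (-9.60 ± 0.49), Fcmr (-9.21 ± 0.75), Ms4a1 (-8.59 ± 0.78) and Ly6d (-8.52 ± 0.60), which are genes of B lineage cells, the neutrophil granule genes Ngp (-9.59 ± 0.44) and S100a9 (-8.55 ± 0.56), and the iron exporter Slc40a1 of red pulp macrophages (-8.60 ± 0.76). Each had a limma adjusted p of at most 0.000123.

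Glycolysis and hypoxia genes rose, with 26 of 28 higher and 0 lower (27 higher adjusted over the list alone) and a median of 2.98. The list's adjusted p was 1.73e-15, and adjusted p = 0.178 with an estimated correlation, range 3.56e-37 to 0.178 over alternatives. Among them were Vegfa, the angiogenic growth factor (6.77 ± 0.28, SE), the lactate exporter Slc16a3 (5.64 ± 0.21) and Pgam1 (3.60 ± 0.18). Alternative activation genes had 20 higher and 1 lower of 26 (22 and 1 adjusted over the list alone), with a median of 3.09 (adjusted p = 1.10e-09, and adjusted p = 0.152 with an estimated correlation, range 1.95e-22 to 0.152 over alternatives). Mrc1 rose by 1.09 ± 0.28 and Cd274 by 2.34 ± 0.64. Macrophage identity genes had 16 higher and 0 lower of 20 (19 higher adjusted over the list alone; adjusted p = 2.73e-09, and adjusted p = 0.127 with an estimated correlation, range 4.24e-21 to 0.127 over alternatives). Among them were Cd14, a co-receptor for endotoxin (6.08 ± 0.23), and Lyz2 (4.09 ± 0.19). As B and T cell markers summed far higher in WT_SP, a different share of macrophages in the sorted samples cannot be told apart from this rise. Lysosome genes had 17 higher and 1 lower of 20, both over all genes and adjusted over the list alone, with the protease gene Ctsl at 4.99 ± 0.24 (adjusted p = 4.15e-08, and adjusted p = 0.236 with an estimated correlation, range 1.47e-17 to 0.236 over alternatives).

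Inflammatory mediators had 17 higher and 3 lower of 21 (17 and 4 adjusted over the list alone; adjusted p = 4.78e-06, and adjusted p = 0.279 with an estimated correlation, range 1.85e-14 to 0.279 over alternatives). Cxcl2 rose from 12.0 ± 2.56 to 1623 ± 313 CPM. Chemokines for T cells and monocytes had 9 higher and 2 lower of 13 (9 and 3 adjusted over the list alone), with a median of 4.81 (adjusted p = 7.52e-05, and adjusted p = 0.127 with an estimated correlation, range 3.05e-11 to 0.127 over alternatives). Complement and Fc receptor genes had 9 higher and 1 lower of 10 (the same counts adjusted over the list alone; adjusted p = 6.18e-05, and adjusted p = 0.236 with an estimated correlation, range 3.5e-11 to 0.236 over alternatives).

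In lipid metabolism, cholesterol synthesis genes had 17 higher and 1 lower of 25 (19 and 1 adjusted over the list alone) with a median of 1.29 (adjusted p = 2.36e-05, and adjusted p = 0.152 with an estimated correlation, range 1.95e-10 to 0.152 over alternatives). Sqle, squalene epoxidase, rose by 2.35 ± 0.26 and Cyp51 by 2.08 ± 0.27 on the log2 scale (SE), while Srebf2 at -0.17 ± 0.16 and Srebf1 at 0.18 ± 0.18 did not pass. Lipid uptake, storage and efflux genes had 15 higher and 4 lower of 25 (16 and 4 adjusted over the list alone; adjusted p = 0.00204, and adjusted p = 0.222 with an estimated correlation, range 4.4e-07 to 0.222 over alternatives). They were led by the scavenger receptor gene Msr1 (7.61 ± 0.21) and the lipid sensor Trem2 (7.77 ± 0.41). Fatty acid synthesis genes had 10 higher and 4 lower of 20, both over all genes and adjusted over the list alone, and the list was not called (adjusted p = 0.152). Fasn fell by 0.71 ± 0.22, and Scd1, a desaturase, fell from 329 ± 11.3 to 22.6 ± 9.62 CPM.

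Within the type I interferon list, Cxcl10, a T cell chemoattractant, rose from 4.94 ± 0.684 to 185 ± 24.7 CPM, Ifitm3 by 2.22 ± 0.22 and Oas1g by 2.12 ± 0.21, while Helz2 fell by 2.18 ± 0.23 (log2, SE). Adjusted over the list alone, 14 rose and 16 fell, the median was -0.25, and the list was not called (adjusted p = 0.543). Irf7 stood at 0.09 ± 0.27, Isg15 at 0.44 ± 0.23 and Ifit1 at 0.19 ± 0.70, none past the limma test. Ifit1 stood at 0.90 and Irf7 at 0.31 without WT_TAM replicate 4, and at -0.22 and -0.06 without WT_TAM replicate 2. Ifnb1 was read at 0.703 ± 0.839 CPM in WT_TAM (SD, n = 4) and 0.0759 ± 0.0772 CPM in WT_SP (SD, n = 3) and was not tested. Interferon gamma induced genes had 9 higher and 0 lower of 20, both over all genes and adjusted over the list alone (adjusted p = 0.000853, and adjusted p = 0.432 with an estimated correlation, range 3.01e-07 to 0.432 over alternatives). Without WT_TAM replicate 4, 18 were higher in the list. Cxcl9 stood at 4.62 ± 0.33 and Gbp2 at 2.68 ± 0.21. Interferon production and nucleic acid sensing had 3 higher and 5 lower of 20, with the same counts adjusted over the list alone (adjusted p = 0.952). Socs1, an inhibitor of cytokine signalling, rose by 1.8 ± 0.25, while Tlr9 and the kinase gene Jak1 fell, with log2 fold changes of -1.84 ± 0.25 and -1.3 ± 0.30. In this list the median of -0.11 and the mean of -0.02 were negative while the test's direction was up.

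ATF4 targets had 10 higher and 1 lower of 18 (adjusted p = 0.00416, and adjusted p = 0.236 with an estimated correlation, range 1.01e-05 to 0.236 over alternatives). Cell cycle genes had 17 and 1 of 34 (0.00478, and adjusted p = 0.602 with an estimated correlation, range 3.63e-05 to 0.602 over alternatives). The oxidative stress response had 8 and 1 of 16 (0.0125, and adjusted p = 0.231 with an estimated correlation, range 9e-05 to 0.231 over alternatives). Adjusted over the list alone the counts were 10 and 1, 19 and 2, and 8 and 2. For the cell cycle, 19 became 10 without WT_TAM replicate 1 and 2 without WT_SP replicate 2 or 3. Oxidative phosphorylation genes had 10 higher and 1 lower of 26 (3 and 1 adjusted over the list alone; adjusted p = 0.0276, and adjusted p = 0.470 with an estimated correlation, range 0.00345 to 0.47 over alternatives). Without WT_TAM replicate 4, 17 were higher and 3 lower in the list. The call was lost without WT_SP replicate 3 (adjusted p = 0.0546), with library factors left out (0.276) and with the deposited values as they stand (0.124). Unfolded protein response genes had 8 higher and 1 lower of 17, the same adjusted over the list alone (adjusted p = 0.0305, and adjusted p = 0.602 with an estimated correlation, range 0.00098 to 0.602 over alternatives). This call was lost without WT_TAM replicate 1 (0.0515), WT_TAM replicate 2 (0.0534), WT_SP replicate 2 (0.0502) or WT_SP replicate 3 (0.0616). It was also lost with library factors left out (0.155), with the deposited values as they stand (0.0828) and by fry (0.0785). In the list, 8 higher became 5 without WT_TAM replicate 1 or 2, 13 without WT_TAM replicate 4, 4 without WT_SP replicate 2 and 3 without WT_SP replicate 3. Lists not called were FoxO targets (adjusted p = 0.218), MHC class I presentation (0.484), fatty acid oxidation (0.60), MHC class II presentation (0.860) and mTOR complexes and AKT (0.885). In the class II list, H2-Ob and H2-Oa, which are expressed in B cells, fell, with log2 fold changes of -5.24 ± 0.22 and -4.80 ± 0.23, while the protease gene Ctss rose by 2.71 ± 0.16, and its median of 0.46 and mean of -0.39 differed in sign.

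Red pulp macrophage genes of the spleen had 14 lower and 4 higher of 22, both over all genes and adjusted over the list alone (adjusted p = 0.000906, and adjusted p = 0.334 with an estimated correlation, range 3.34e-08 to 0.334 over alternatives). Spic, the factor that specifies these cells, had 1.69 ± 0.581 CPM in WT_TAM and 162 ± 12.1 CPM in WT_SP, and Vcam1 and Itgad fell, with log2 fold changes of -4.06 ± 0.20 and -7.13 ± 0.43, while Clec4n rose by 2.68 ± 0.18. Markers of other cells moved with them. B cell and plasma cell markers, all 15 lower, summed to 153 ± 92.2 CPM in WT_TAM and 31811 ± 3500 CPM in WT_SP (adjusted p = 8.12e-11, and adjusted p = 0.236 with an estimated correlation, range 2.71e-22 to 0.236 over alternatives). The light chain gene Igkc stood at -8.77 ± 0.40. T cell markers, all 16 lower, summed to 197 ± 35.6 and 2310 ± 89.1 CPM (adjusted p = 8.12e-11, and adjusted p = 0.152 with an estimated correlation, range 2.89e-24 to 0.152 over alternatives). NK cell genes had 9 lower and 1 higher of 12 (0.000548, and adjusted p = 0.381 with an estimated correlation, range 7.97e-08 to 0.381 over alternatives). Neutrophil genes had 8 lower of 11 (0.000159, and adjusted p = 0.240 with an estimated correlation, range 1.33e-10 to 0.24 over alternatives). Erythroid genes had 11 lower of 11 (0.000108, and adjusted p = 0.360 with an estimated correlation, range 1.06e-09 to 0.36 over alternatives). Platelet genes had 8 lower and 1 higher of 10 (0.00391, and adjusted p = 0.240 with an estimated correlation, range 1.17e-05 to 0.24 over alternatives), although their sum, dominated by 1 gene, Pf4, was 600 ± 322 against 139 ± 30.4 CPM. Against the direction of their lists, Gzmb of the NK cell list rose by 1.23 ± 0.35 and Retnlg of the neutrophil list stood at 0.74 ± 0.37, or 0.43 without WT_TAM replicate 1. Adjusted over the list alone, the counts of these 6 lists were the same as over all genes.

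Fibroblast genes had 12 higher and 1 lower of 13, the same adjusted over the list alone (adjusted p = 3.24e-05, and adjusted p = 0.279 with an estimated correlation, range 3.29e-10 to 0.279 over alternatives). They summed to 1259 ± 516 CPM in WT_TAM and 68.7 ± 36.2 CPM in WT_SP. Tumor epithelium markers summed to 315 ± 102 and 26.1 ± 3.75 CPM, with Cdh1 at 5.56 ± 0.40 and Sox9 at 6.18 ± 0.62 (list adjusted p = 0.161). Of 17 summed marker lists, 10 differed by the exact permutation test (p = 0.0286 each, the smallest possible, adjusted 0.0486): T, NK and B cells, neutrophils, monocytes, plasmacytoid dendritic cells, tumor epithelium, fibroblasts, endothelial and erythroid cells. Mitochondrial genome transcripts had 9 of 13 higher (10 adjusted over the list alone; adjusted p = 0.00919, and adjusted p = 0.602 with an estimated correlation, range 0.000267 to 0.602 over alternatives). This call was lost without WT_TAM replicate 4 (adjusted p = 0.205). In the list, 10 became 1 without WT_TAM replicate 2 and 0 without WT_TAM replicate 4 or any WT_SP library. Dissociation and immediate early genes had 10 higher and 3 lower of 18, the same adjusted over the list alone (adjusted p = 0.00919, and adjusted p = 0.599 with an estimated correlation, range 3.13e-05 to 0.599 over alternatives). Camera did not call plasmacytoid dendritic cells (adjusted p = 0.0685), dendritic cells (0.287), eosinophils, basophils and mast cells (0.380), cytosolic ribosomal proteins (0.382), endothelial cells (0.455) or monocytes (0.860). Cytosolic ribosomal proteins were lower without WT_TAM replicate 4 (adjusted p = 1.47e-06, range 1.26e-06 to 0.916 over alternatives). Plasmacytoid dendritic cells were lower without WT_SP replicate 1 (0.0471, range 0.000233 to 0.240). Xist had 83.1 ± 18.1 and 127 ± 25.9 CPM (limma adjusted p = 0.0528).

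Both comparisons use the WT_TAM libraries, so their chance values are shared. Among 12733 genes tested in both, 0 were called in both, since the first called 0. At an unadjusted p of 0.05, 740 genes were lower in KO_TAM than in WT_TAM and higher in WT_TAM than in WT_SP, 371 were higher and then lower, 306 were higher in both and 128 lower in both. If calls in the comparisons were independent, the expected counts would be 361, 252, 312 and 292. Genes higher in both were thus close to the expected count, and genes lower in both were fewer. These expected counts take no account of the common libraries, which alone favour opposite directions. In 100 simulations of unchanged groups that share WT_TAM, the mean counts were 50.8, 42.9, 0.38 and 0.51. As the simulated groups hold no change in either comparison, these means show the direction only and are no measure for the observed counts. The correlation of the fold changes was -0.26, within the simulated range of -0.92 to 0.61 (mean -0.41), while their covariance was -0.24 against a simulated mean of -0.05. With WT_TAM split into pairs of libraries the correlation averaged -0.17, from -0.23 to -0.11. Of 12 lists called in both comparisons, 8 had opposite directions, among them the cell cycle, cholesterol synthesis, ATF4 target and fibroblast lists, and the share of this that comes from the common libraries is left open.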

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

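The tests of the altered values, of Lyz2, of exchanged labels and of other splits of the genotype gene calls were chosen only after the results were seen. Of 200 groups of 4 libraries, 26 had 1 library far from the others by a gap-to-range ratio, where chance gives about 10 at 1 in 20. WT_TAM replicate 4 was that library in 11 of them and KO_TAM replicate 2 in 10.

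In 35 genes of the genotype table, 98 values were not whole reads, and those of interferon list genes were mostly raised in KO_TAM or lowered in WT_TAM, while those of lipid synthesis genes moved the other way. A difference between the libraries is argued against, since 46 of the 49 such WT_TAM values differ from the value of the same library in the site table by a whole number, within 1e-05. A wrong gene length or library factor in the recovery is argued against too, since 180 of the 278 non-zero values of these genes were whole at the same length, and 1 of the 98 became whole with the factor of another library. With the values as deposited, library factors differed from those in the table by up to 0.000442 on the natural log scale, against 5.12e-11 with restored reads, which is consistent with values that changed after the factors were computed. How and why they came to differ cannot be read from the tables, and changes that left whole reads would not be seen.

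WT_TAM replicate 4 and KO_TAM replicate 2 lay apart, at root mean square log2 distances of 1.02 and 0.784 from their groups, against 0.587 to 0.646 for the other 6. With a gene length trend per library removed, the smaller of the 2 distances was 0.771, above 0.605, the largest of the others, so such a trend is not the whole cause. Without the 50 genes with most reads of each library it was 0.784, above 0.643, the largest of the others. The distance thus does not lie in those genes themselves. As their removal moved no library by more than 0.00428, it does not decide whether they act by taking reads from other genes. Exchanged labels of these 2 libraries are argued against, since each correlated better with its own group, by at least 0.0284, against at most 0.0197 for the other 6. Mapkap1 goes the other way in part, at 30.7 CPM in WT_TAM replicate 4, below all KO_TAM libraries, and in KO_TAM replicate 2 at 54.1 CPM, the highest of its group though below the other WT_TAM libraries. A difference in RNA quality or cell makeup may remain and was not tested, nor was a biological explanation.

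Lyz2 was lower in all KO_TAM libraries, with a log2 fold change of -1.64 and a limma adjusted p of 0.143. A lower share of macrophages in KO_TAM is argued against as the whole cause, since the median of the other 19 macrophage identity genes was -0.11. Of these, 13 lay below 0 and 1 was as low as Lyz2, so a part in the change is not excluded. The libraries that lay apart are not the whole cause, since without both the change was -0.98 (limma adjusted p = 0.0360, range 0.0360 to 0.412 over alternatives). The Cre sits in the Lyz2 locus, so a candidate explanation is less Lyz2 transcript from the allele that holds it, a hypothesis that cannot be separated here from an effect of Sin1 loss because no mice with Cre alone were among the groups.

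In WT_TAM replicate 4 the ratio was 0.854 for Mcm6, 0.902 for Rplp0, 0.837 for Rpl13, 0.904 for Cd274, 0.865 for Siglecf, 0.837 for Ifitm3 and 0.831 for Lck. It was also 0.965 for the summed NK cell markers, 0.956 for the summed ribosomal proteins and 0.88 for the first principal component. In KO_TAM replicate 2 it was 0.959 for Rplp0, 0.831 for Rpl13, 0.877 for Retnlg, 0.901 for Ccl6, 0.836 for Lyz2, 0.839 for Trem2, 0.874 for Cyp51, 0.852 for Jak1, 0.901 for Fdft1 and 0.83 for Top2a, the last chosen after its values were seen. Elsewhere it was 0.87 for Isg15 in WT_TAM replicate 1, 0.91 for Slc3a2 and 0.899 for Vegfa in WT_TAM replicate 3, 0.913 for Itgad in WT_TAM replicate 2, and 0.863 for the summed erythroid markers in KO_TAM replicate 3.

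Of 35 splits of the 8 tumor libraries, only the real 1 gave as many as 2368 genes at an unadjusted p under 0.05 (highest other 1104). That share of 1 in 35 is the smallest possible, so it argues against chance without excluding it. For the 16 lists chance is not argued against, as 4 of 35 splits reached that number (highest other 18). Splits that exchange only 1 library per group would keep part of a genotype difference, so this share does not exclude such a difference either. Without the libraries that lay apart the 10 splits are too few for a share under 0.05, with 65 genes in the real split, reached by 1, and 0 as the highest other. In WT_TAM against WT_SP, only the real split of 35 reached the 6651 genes (highest other 1321), which argues against chance with the same limit. The 25 lists were reached by 2 of 35 splits (highest other 25). The other of these 2 had 4441 genes at an unadjusted limma p under 0.05. Splits that keep the WT_SP libraries together still hold part of the site difference, so this share does not decide on chance.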

How the results depend on the processing

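Alternatives named here as pseudocounts, library factors left out, array weights, deposited values, altered cells and the removal of both libraries that lay apart were chosen after the data were seen. For KO_TAM against WT_TAM, limma trend called 0 genes (2368 at an unadjusted p under 0.05), as did voom (2228), upper-quartile factors (2348), at least 1 CPM (2411), library factors left out (2184) and each removal of 1 library (0 to 0 called, 1494 to 2423 unadjusted). It called 98 without a filter, 83 with all groups in 1 fit, 387 with array weights, 4 with the deposited values as they stand, 4 with the altered cells as deposited and 65 without WT_TAM 4 and KO_TAM 2. The cause was not tested, except that the 4 calls with altered cells as deposited are genes with such cells. Of 16 lists called, 0 were called with an estimated correlation and 1 by fry, and removing 1 library gave 16 to 21. For WT_TAM against WT_SP, 6651 genes were called, and 4980 to 9133 without 1 library, the most without WT_TAM replicate 4. Of 25 lists, 0 were called with an estimated correlation and 22 by fry, which called 28 in all. Without 1 library 23 to 26 lists were called. The overlap of calls was 0, and 48 without WT_TAM 4 and KO_TAM 2. B2m reversed, at -0.0105 with library factors left out against 0.47, since that setting moved the median of all genes. Replicate numbers did not pair the samples, with correlations of 0.05, 0.11, -0.16 and 0.20 for the genotype and -0.00, -0.09 and 0.10 for the site, and best matches for both partners only at site replicate 3. A replicate block gave 0 and 9004 genes and 19 and 25 lists, and WT_TAM replicate 4 has no site partner. Median-of-ratios factors equal the authors' factors, so all 311 results under them had the same values, which is no evidence of stability, and they are left out of the tallies here. Other list results stayed the same in 702 cases, weakened in 38, strengthened in 36 and moved in 24 for the genotype, and 576, 40, 13 and 11 for the site. The summed markers without 1 library passed for 0 lists in the genotype comparison. There a list can pass only if many lists reach the smallest possible p, so this is no evidence of stability. In the site comparison they cannot reach the threshold, so no value is given. DESeq2 and edgeR were not run, since the deposited unit is not counts. The recovered reads, on which voom was run, were not tested with them either.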

Other observations

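Genes named here were chosen after their values were seen. In KO_TAM, 7 ATF4 targets were lower adjusted over the list alone, among them the serine synthesis enzyme genes Phgdh (log2 fold change -1.86) and Psat1 (-0.88) and the asparagine synthetase gene Asns (-1.38), while the cystine transporter gene Slc7a11 stood at 1.26. Among macrophage identity genes, the complement genes C1qa, C1qb and C1qc stood at -1.29, -1.07 and -1.08 and the chemokine receptor gene Cx3cr1 at -1.76, while the integrin gene Itgam stood at 0.56. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 stood at -0.66, -0.73 and -0.75 and their transactivator Ciita at -0.59. Reads of the H2 genes are uncertain, because of near-identical copies. None of these passed the limma test over all genes.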
